A study of Mus musculus with 12 samples.

How the data were processed

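RNA of 12 livers of male mice was measured on Affymetrix GeneChip whole-transcript arrays, 1 array per liver, in 3 groups of 4: WT untreated, WT given LPS at 1 µg/kg, and S534A given the same dose. The deposited values are on the log2 scale. Per the submitters' processing notes, the authors made them with RMA, which corrects background, quantile normalises the probes and summarises them per probe set. The version of RMA and the genome build behind the probe annotation are not given in the sources used here. The values ran from 3.43 to 14.48 and were used without further normalisation. Checked on the values themselves, the distributions were similar but not identical. The upper quartile ran from 8.04 on WT LPS replicate 2 to 8.33 on untreated replicate 4. Replicates are numbered within each group in the order of their labels.

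The table held 35556 probe sets. Of these, 21789 carried 1 gene symbol, 1621 several and 12146 none. The latter 2 kinds were left out of the gene tests and counted apart. Entrez identifiers matched the GRCm38.p6 gene table for 21698 of the 1-symbol probe sets. The other 91 kept the symbol of the deposited annotation. That gene table served only for names and for which genes neighbour each other. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 12 arrays was used, which left 19938 genes. No filter on dim genes was applied.

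Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 12 arrays, with 9 residual and 3.54 prior degrees of freedom. The comparisons were WT LPS against WT untreated, S534A LPS against WT LPS, S534A LPS against WT untreated, and the mean of both LPS groups against WT untreated. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, with no fold threshold; tests were two-sided. Differences are given in log2 with limma's standard error, and group means with the SD of the 4 arrays.

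A total of 41 gene lists and marker lists (570 symbols, 516 of them measured, 4 under a synonym) were drawn up from general knowledge of the LPS response and of liver cell types. Listed genes without a probe set of their own are not in the counts. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 41 lists of a comparison. Members were also counted after adjustment over the list alone. Genes raised or lowered at least 2-fold by LPS in the mean of both LPS groups were tested with camera in the genotype comparison. The mean over a list's members per array was compared between groups with an exact two-sided permutation test. Fisher's exact test, two-sided, compared called genes within 20 Mb of Rela with all other placed genes. The same test was run for each chromosome, with Benjamini-Hochberg adjustment over the chromosomes.

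Named genes followed a rule set, like the comparisons, lists and tests above, before the data were examined. It named, in each of the first 2 comparisons, the 8 largest rises and 8 largest falls past the threshold with fully separated groups. Where fewer than 8 passed in a direction it named all that passed and, to make up 5, those with the smallest p. It also named the 2 to 4 members with the smallest p of each list described, and in every case Rela, Saa1, Tnf, Il1b, Il6, Cxcl1, Ccl2, Nfkbia and Tnfaip3. Predicted genes and loci without a name, by the form of the symbol, were left out of the first part.

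Both procedures were tested on simulated data with the spread of these arrays, 50 changed genes per size among 19938. For S534A LPS against WT LPS, 62% of genes changed by 0.5, 90% at 0.7, 96% at 1 and 100% at 2 were recovered, with 9 false calls. For WT LPS against untreated the shares were 66%, 80%, 98% and 100% with 12 false calls, and for S534A LPS against untreated 64%, 94%, 100% and 98% with 13. No recovered gene had the wrong sign. Each simulation changed 200 genes. Where fewer genes are called, as between the genotypes, the adjusted threshold is stricter and the recovered shares can be lower. A list shifted by 0.5 was called in each comparison and 0 of 19 unshifted lists were. Smaller list shifts were not simulated. The simulated genes varied independently of each other, so this does not cover lists with correlated members. In the real data the estimated correlation was 0.37 for the type I interferon list.

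Alternatives set in advance were each array left out in turn, other thresholds, a filter on dim genes (11964 genes kept), every probe set or the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, repeated quantile normalisation, median centring, a fit of only the 2 groups compared, a replicate block, other fold thresholds for LPS-responsive genes, and other windows around Rela. After the data were seen, a fit without 3 arrays that carried pancreas transcripts, a neutrophil marker covariate and a clock covariate were added. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.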

Results

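A total of 12 livers of male mice on the C57Bl/6 background were profiled with Affymetrix GeneChip arrays, in 3 groups of 4 livers: wild-type (WT) mice left untreated, WT mice given lipopolysaccharide (LPS) at 1 µg/kg, and S534A mice given the same dose. LPS, a component of the outer membrane of Gram-negative bacteria, signals through Toll-like receptor 4 to NF-kB and to the interferon regulatory factors. S534A mice carry a serine-to-alanine substitution knocked in to p65, the NF-kB subunit encoded by Rela. The allele was made in PTL1 embryonic stem cells, and the line was backcrossed 5 times to C57Bl6/J. The time between LPS and tissue collection is not given in the sources used here. Untreated S534A livers were not analysed here, so a genotype difference already there before LPS and one in the response to LPS cannot be told apart. The untreated arrays are titled by another scheme than the LPS arrays. If they were run separately, batch and LPS treatment cannot be told apart either.

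Each array gave log2 values for 35556 probe sets, from 3.43 to 14.48. The medians of the 12 arrays lay between 6.15 and 6.32, and arrays of one group correlated with each other at 0.983 to 0.996 across probe sets. No pair of arrays shared more than 0.0422% identical values, so no array was a copy of another. The labels count livers and do not say in so many words that each came from a separate animal. The p-values measure the spread between these samples. The number of arrays limits the precision of every value.

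Rela itself (probe set 10460631) read 9.96 ± 0.14 (SD, n = 4) in untreated WT livers, 11.11 ± 0.08 in WT LPS livers and 11.20 ± 0.06 in S534A LPS livers. It was 2.21-fold higher after LPS in WT mice (log2 difference 1.14 ± 0.07, SE; limma adjusted p = 1.45e-07). Between the LPS-treated genotypes it differed by 0.09 (95% interval -0.07 to 0.25; adjusted p = 1). This probe set measures the transcript and cannot see a substitution in the protein, so it does not check which mice carried the allele.

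The first comparison asked what LPS changed in the WT liver. Interferon-induced transcripts rose most, and the serum amyloid A genes Saa1 and Saa3 were also among the 8 largest rises. Among genes whose 4 arrays of each group were fully separated, the largest rises were those of Ifit3b (probe set 10462621; log2 difference 5.65 ± 0.13, SE; adjusted p = 1.09e-11), Ifit2 (5.53 ± 0.14), Rsad2 (5.46 ± 0.16), Ifit1 (5.25 ± 0.11), Cmpk2 (4.99 ± 0.13), Saa1 (4.89 ± 0.43), Saa3 (4.78 ± 0.16) and Gbp9 (4.50 ± 0.10). These are 50.2-fold for Ifit3b down to 22.7-fold for Gbp9. The Ifit genes and Rsad2, which encodes viperin, are antiviral interferon targets. Saa1 and Saa3 encode serum amyloid A proteins, and Gbp9 a guanylate-binding protein. Ifit3b and Saa1 have near-identical neighbours in their gene families, and probes shared with those were not separated here.

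The largest falls in WT liver after LPS were those of Fam13a (probe set 10545045; -2.87 ± 0.16; adjusted p = 3.16e-08), Slc40a1 (-2.82 ± 0.19), Clec2h (-2.79 ± 0.20), Sucnr1 (-2.71 ± 0.14), Nrep (-2.64 ± 0.16), Hsd3b2 (-2.50 ± 0.18), Adh6-ps1 (-2.30 ± 0.21) and Nr1i3 (-2.23 ± 0.28). Fam13a read 7.31-fold and Slc40a1 7.05-fold lower after LPS. Slc40a1 encodes ferroportin, the iron exporter, Sucnr1 the succinate receptor, and Nr1i3 the nuclear receptor CAR, a regulator of drug metabolism. Adh6-ps1 carries a pseudogene symbol, and signal from related alcohol dehydrogenases was not separated.

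In all, 1863 genes rose and 3120 fell among the 19938 tested (limma, adjusted p under 0.05, n = 4 per group), 4983 in all. Of these, 417 rose and 205 fell by at least 2-fold. Without the 3 arrays that carried exocrine pancreas transcripts (WT LPS replicates 2 and 3 and S534A LPS replicate 3), an alternative chosen after the data were seen, 1745 genes fell. The median over all genes was 0.02, and the list shifts are relative to it. RMA makes the distributions of the arrays near equal, so this median cannot show whether expression shifted in general.

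Both interferon programmes rose as groups. All 28 measured members of the type I interferon response list rose, also when adjusted over the list alone, with a median log2 difference of 3.00 (camera adjusted p = 5.65e-46; adjusted p = 0.00547 with an estimated correlation). Parp14 rose by 3.11 ± 0.06, Usp18, the interferon-induced ISG15 protease, by 3.96 ± 0.09, and Ifit1 as given above. Of 17 interferon-gamma GTPase and antigen processing genes, 16 rose (17 adjusted over the list alone; median 2.28; camera adjusted p = 5.43e-28, or 0.00265 with an estimated correlation). Gbp7 rose by 3.52 ± 0.09 and Cd274, which encodes the checkpoint ligand PD-L1, by 3.68 ± 0.11. Cd274 was thus 12.8-fold higher after LPS.

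NF-kB feedback genes, chemokines and cytokines rose too. Of 14 NF-kB subunit and feedback genes, 12 rose (13 rose and 1 fell adjusted over the list alone; median 0.90; camera adjusted p = 2.79e-11, or 0.00173 with an estimated correlation). Nfkb2 rose by 2.19 ± 0.07, Nfkbie by 2.17 ± 0.09, Tnfaip3, which encodes the deubiquitinase A20, by 1.61 ± 0.10, and Nfkbia, which encodes the inhibitor IkB-alpha, by 0.67 ± 0.15 (adjusted p = 0.00434). Of 18 chemokine genes 13 rose, the same count adjusted over the list alone (median 1.42; camera adjusted p = 1.13e-13, or 0.00265 with an estimated correlation). Cxcl10 was 21.7-fold, Cxcl9 17.6-fold, Ccl3 14.1-fold, Ccl5 13.6-fold, Ccl2 9.20-fold and Cxcl1 2.71-fold higher after LPS. Cxcl1 was the most variable of these (log2 difference 1.44 ± 0.36; adjusted p = 0.0104). Nfkbia and Cxcl1 no longer passed without the 3 arrays with pancreas transcripts. Of 22 cytokine genes 8 rose (9 adjusted over the list alone; median 0.25; camera adjusted p = 1.31e-05, or 0.0461 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose by 3.24 ± 0.14, Tnf by 2.27 ± 0.08 and Il1b by 1.61 ± 0.15. Il6 read 4.61 ± 0.03 (SD) before and 4.92 ± 0.16 after LPS, near the floor of the array, and did not pass (adjusted p = 0.167).

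The acute phase response was broad: 21 of 23 acute phase genes rose (22 adjusted over the list alone; median 0.89; camera adjusted p = 2.32e-16, or 0.0201 with an estimated correlation). Beside Saa1 and Saa3, the protease inhibitor gene Serpina3n rose by 0.89 ± 0.05 and Cd14, the LPS co-receptor, by 2.78 ± 0.17. In the IL-6 family and STAT3 list 11 of 13 genes rose (12 adjusted over the list alone; median 0.84; camera adjusted p = 1.22e-09, or 0.00265 with an estimated correlation), among them Stat3 by 1.38 ± 0.06 and the oncostatin M receptor gene Osmr by 2.28 ± 0.15. Of 19 Toll-like receptor pathway genes 12 rose and 1 fell, with the same counts adjusted over the list alone (median 0.58; camera adjusted p = 1.53e-08, or 0.0461 with an estimated correlation). Tlr2 rose by 4.40 ± 0.10 and Irak3, an inhibitor of the pathway, by 3.64 ± 0.11. Of 16 cell survival and death genes 12 rose (14 adjusted over the list alone; median 0.63; camera adjusted p = 2.26e-11, or 0.00265 with an estimated correlation). Mlkl, the effector of necroptosis, rose by 3.36 ± 0.16 and the death receptor gene Fas by 2.14 ± 0.11.

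Of 11 endothelial activation and haemostasis genes 7 rose and 1 fell, with the same counts adjusted over the list alone (median 0.57; camera adjusted p = 0.00134, or 0.024 with an estimated correlation). Icam1 rose by 2.40 ± 0.08, Thbs1 by 2.07 ± 0.11 and Vcam1 by 2.17 ± 0.14. Of 9 glucocorticoid and metallothionein genes 4 rose (5 adjusted over the list alone; median 0.98; camera adjusted p = 2e-05, or 0.0461 with an estimated correlation). Mt1 was 9.99-fold and Mt2 12.5-fold higher, and the glucocorticoid target Zbtb16 rose by 2.38 ± 0.09. With an estimated correlation some of these list calls depended on single arrays. The cytokine call held only without WT LPS replicate 3 (adjusted p up to 0.0708 without other arrays). The Toll-like receptor call held only without WT untreated replicate 4 or WT LPS replicate 2 (up to 0.0715), and the glucocorticoid call only without WT untreated replicate 1, S534A LPS replicate 2 or WT LPS replicate 4 (up to 0.0884). Without the 3 arrays with pancreas transcripts the cytokine and glucocorticoid calls were lost too (adjusted p = 0.0533 and 0.108).

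Markers of blood-derived myeloid cells rose as well. Of 13 neutrophil markers 10 rose, the same count adjusted over the list alone (median 0.66; camera adjusted p = 9.85e-09, or 0.0201 with an estimated correlation). Retnlg rose by 2.14 ± 0.10 and S100a9 by 1.77 ± 0.09. Of 6 monocyte markers 4 rose (5 adjusted over the list alone; median 0.59; camera adjusted p = 0.00027, or 0.0392 with an estimated correlation), among them Plac8 by 1.62 ± 0.17 and F13a1 by 1.10 ± 0.12. The monocyte call with an estimated correlation held only without S534A LPS replicate 2, WT LPS replicate 1 or WT LPS replicate 2 (adjusted p up to 0.0638 without other arrays). Of 12 Kupffer cell and macrophage markers 1 rose and 4 fell (2 rose and 5 fell adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.137, or 0.655 with an estimated correlation), except with the preset one without WT LPS replicate 1 (0.038) or 4 (0.048). Marco rose by 1.40 ± 0.14, whereas Clec4f fell by 0.76 ± 0.11 and Vsig4 by 1.25 ± 0.21 on the log2 scale.

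Genes of liver metabolism and of resident non-parenchymal cells mostly fell where they changed. Of 18 genes of bile acid synthesis and transport 9 fell (1 rose and 11 fell adjusted over the list alone; median -0.36; camera adjusted p = 0.00212, and adjusted p = 0.316 with an estimated correlation). Akr1d1 fell by 0.75 ± 0.10, the canalicular exporter gene Abcc2 by 0.71 ± 0.11 and the uptake transporter gene Slco1a4 by 1.29 ± 0.24. Of 16 cholesterol synthesis genes 8 fell (1 rose and 8 fell adjusted over the list alone; median -0.38; camera adjusted p = 0.000393, and adjusted p = 0.413 with an estimated correlation). Sc5d fell by 0.67 ± 0.08 and Stard4 by 1.08 ± 0.17. Of 13 lipogenesis genes 1 rose and 6 fell (1 and 7 adjusted over the list alone; median -0.44; camera adjusted p = 0.00504, and adjusted p = 0.362 with an estimated correlation). Gpam fell by 1.27 ± 0.11, Mlxipl by 0.51 ± 0.09 and Srebf1 by 1.11 ± 0.22.

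Of 18 genes of drug-metabolising cytochromes P450 and their receptors 1 rose and 4 fell, with the same counts adjusted over the list alone (median -0.14; camera adjusted p = 0.0186, and adjusted p = 0.447 with an estimated correlation). Nr1i3 and Cyp3a25 (-0.57 ± 0.09) fell, and Cyp2b10 rose by 1.87 ± 0.41. The P450 list no longer passed without WT untreated replicate 4 or WT LPS replicate 2, nor without the 3 arrays with pancreas transcripts (camera adjusted p = 0.0583). Of 13 sinusoidal endothelial markers 1 rose and 6 fell (1 and 10 adjusted over the list alone; median -0.45; camera adjusted p = 0.00102, and adjusted p = 0.431 with an estimated correlation). Kdr, the VEGF receptor gene, fell by 1.59 ± 0.13 and Tek, the angiopoietin receptor gene, by 1.38 ± 0.12, while Lyve1 rose by 1.32 ± 0.15. Of 11 stellate cell and fibroblast markers 4 fell, the same count adjusted over the list alone (median -0.18; camera adjusted p = 0.0431, and adjusted p = 0.185 with an estimated correlation). Lrat, which makes retinyl esters, fell by 1.42 ± 0.27 and Pdgfrb by 0.66 ± 0.13. The stellate list lost its call without any one of WT untreated replicates 1 and 3 and WT LPS replicates 2 and 3, and without the 3 arrays with pancreas transcripts (camera adjusted p = 0.0844). Of 16 unfolded protein response genes 2 rose (1 adjusted over the list alone; median 0.27; camera adjusted p = 0.00771, and adjusted p = 0.37 with an estimated correlation). These were Xbp1 (0.53 ± 0.11) and Creld2 (1.15 ± 0.39; adjusted p = 0.0488), and Creld2 no longer passed without any one of 10 of the 12 arrays (adjusted p up to 0.136), nor without the 3 arrays with pancreas transcripts.

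**Figure D1:**
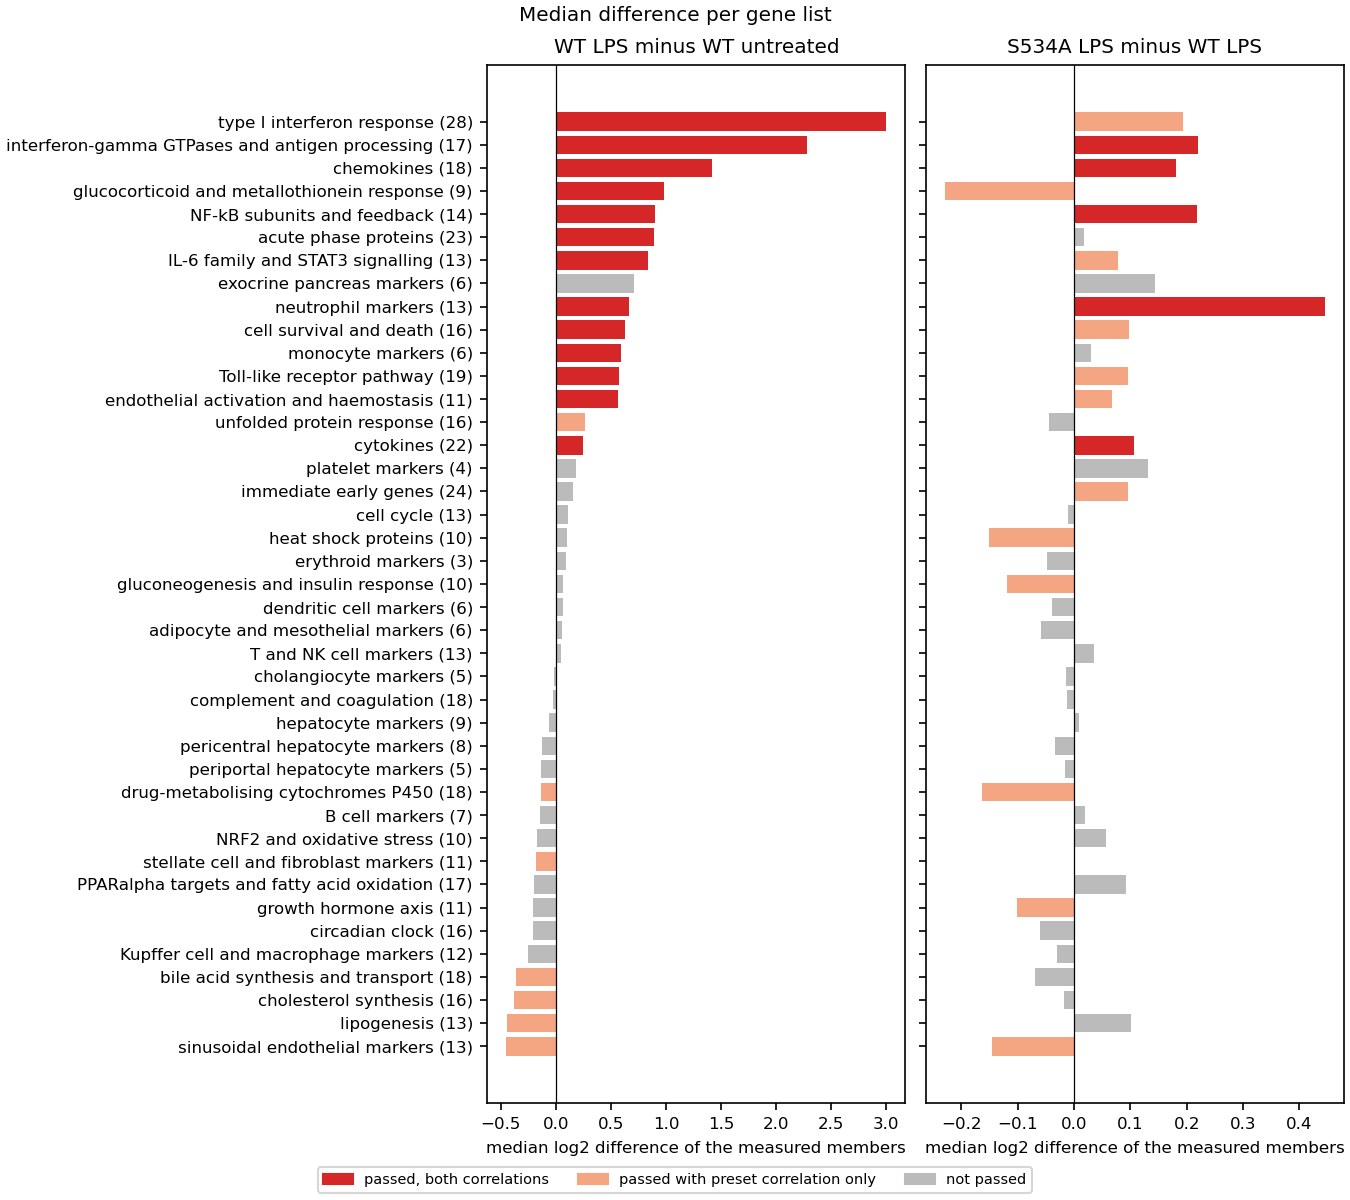
Median log2 difference (x axis) over the measured members of each of the 41 gene lists (y axis, number of measured members in parentheses), for WT LPS minus WT untreated on the left and S534A LPS minus WT LPS on the right, on different scales. Colour marks whether camera's adjusted p passed with the preset and the estimated correlation, with the preset one only, or not; the type I interferon list leads on the left at 3.00 and the neutrophil markers on the right at 0.45.

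The next comparison set S534A against WT mice, both given LPS, and so asked what the p65 substitution changed in LPS-treated livers. In S534A livers the cytokine genes Il1a, Il1b and Il33, of the interleukin-1 family, read higher. Il1a (probe set 10487588) was 2.41-fold higher (9.44 ± 0.11 against 8.17 ± 0.23, SD, n = 4 each; log2 difference 1.27 ± 0.13, SE; adjusted p = 0.00191). WT LPS livers did not differ detectably from untreated ones in Il1a, which read 8.18 ± 0.24 in the latter. Il1b was 2.12-fold (1.09 ± 0.15; adjusted p = 0.0158), Il33 1.94-fold (0.95 ± 0.11; adjusted p = 0.00372) and Socs1, an inhibitor of cytokine receptor signalling, 1.82-fold higher (0.86 ± 0.07; adjusted p = 0.000906, probe set 10437668).

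The other largest differences were those of Mxd1, a MYC-antagonising transcription factor (1.17 ± 0.12), Ch25h, the cholesterol 25-hydroxylase (1.12 ± 0.15), the collagenase gene Mmp13 (1.10 ± 0.15), Zfp296 (1.03 ± 0.16) and Cited2 (0.99 ± 0.16). All 4 S534A arrays lay above all 4 WT LPS arrays for each gene named so far in this comparison. The single gene called lower was Cpeb2, a regulator of mRNA translation (probe set 10521602; -0.83 ± 0.12; adjusted p = 0.0226). The next 4 by p in that direction did not pass: Hsph1 (-0.69 ± 0.12; adjusted p = 0.0585), Armcx1 (-0.37 ± 0.07; 0.0676), Tuft1 (-0.47 ± 0.09; 0.0761) and Glyctk (-0.48 ± 0.09; 0.0761).

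In all, 33 genes were higher and 1 was lower in S534A than in WT livers after LPS (limma, adjusted p under 0.05), 6 and 0 of them by at least 2-fold, against 840 and 308 at an unadjusted p under 0.05. The differences of the 33 ran from 0.43 to 1.27 with a median of 0.70, or 1.62-fold. Ccl3, Cd274, Cxcl11, Retnlg and S100a9 are given with their lists below. The remaining genes, not chosen by the naming rule but listed to complete the set, were Chil1 (0.93), Casp2 (0.89), Hcar2 (0.84), Adm (0.79), Slfn4 (0.70), Bcl6b (0.70), Lpar6 (0.66), Il1f9 (0.64), Tent5a (0.60), Dcp2 (0.57), Reg3g (0.54), Arg2 (0.53), Cd40 (0.53), Ssx2ip (0.49), Hk2 (0.47), Slfn10-ps (0.44), Gata6 (0.44), Bambi (0.43) and Nat8f4 (0.43). The number called depended on single arrays: it was 14, 12, 14 and 12 without S534A LPS replicates 1 to 4 in turn, and 117, 21, 9 and 15 without WT LPS replicates 1 to 4. It was 1 (Socs1) without the 3 arrays with pancreas transcripts, 19 over every probe set, and 344 higher and 132 lower with array weights. With the neutrophil marker mean as a covariate, also chosen after the data were seen, it was 0, and 0 in the other direction. The median of the 33 then read 0.59. Without each of the untreated arrays the count was 26 to 43. No called gene changed sign in any of these. Socs1, Il1a, Mxd1, Hcar2, Il33, Cd274, Ccl3, Bcl6b and Adm were the 9 genes called with each array left out in turn.

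**Figure D2:**
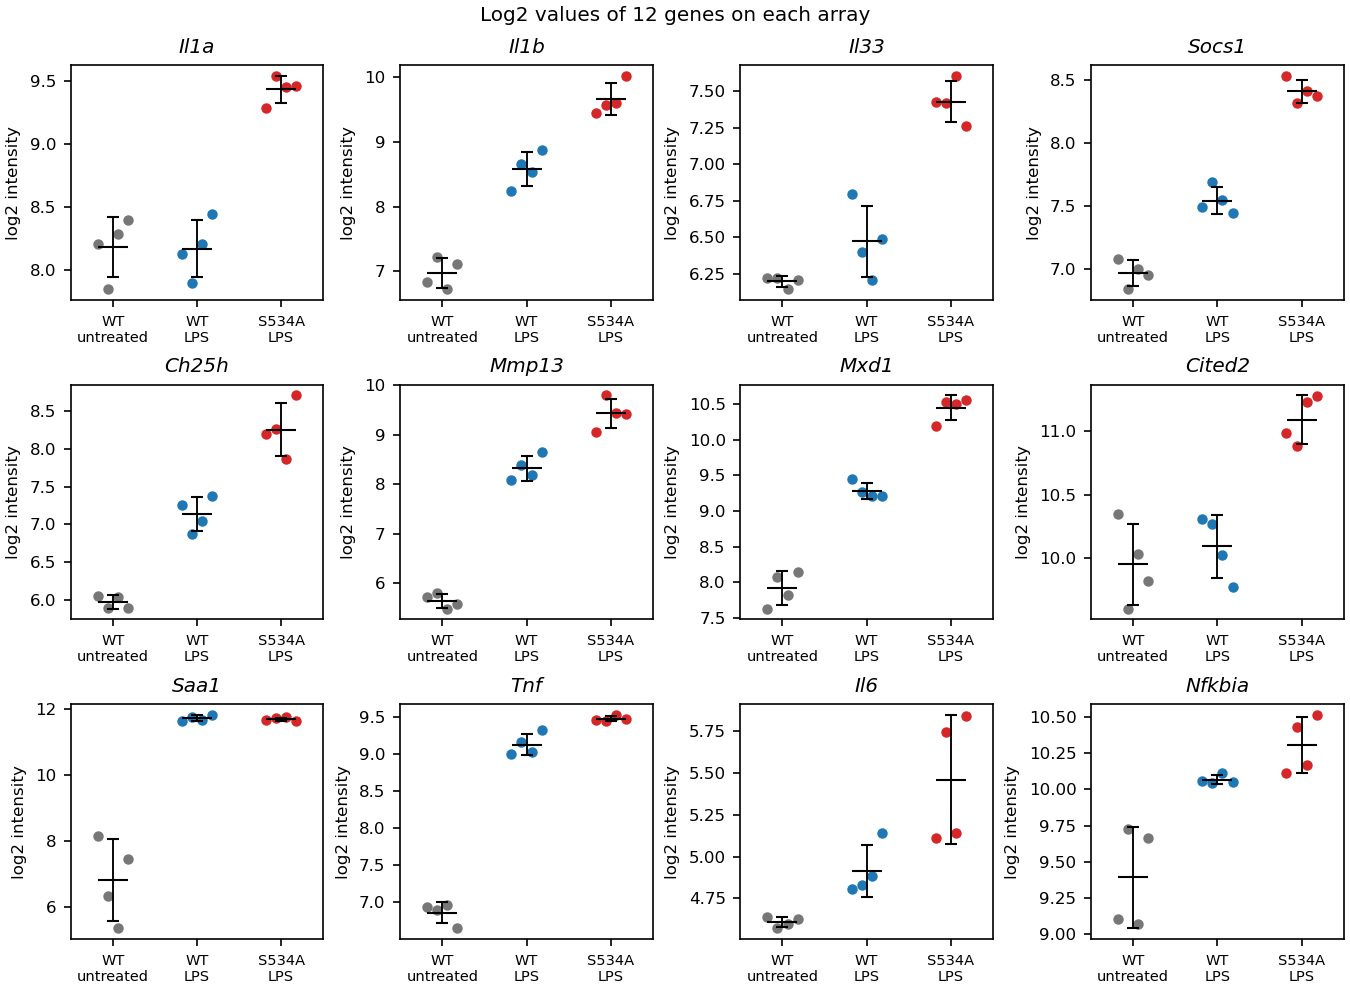
Log2 intensity (y axis, scaled per gene) of 12 genes on each array, by group on the x axis (WT untreated, WT LPS, S534A LPS). Points are arrays, the horizontal bars group means and the error bars ± 1 SD (n = 4); Il1a is higher in the S534A group alone (8.18, 8.17 and 9.44), whereas Saa1 reads alike in both LPS groups (11.72 and 11.69).

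Genes fixed in advance for their part in the response to LPS gave a mixed picture. Il1b passed, as given above. Saa1 differed by -0.03 ± 0.43, Cxcl1 by 0.43 ± 0.36 and Nfkbia by 0.24 ± 0.15 (adjusted p = 1 for each). With single arrays left out the Cxcl1 difference ran from 0.07, without WT LPS replicate 1, to 0.67. Tnf read higher by 0.35 ± 0.08 (adjusted p = 0.179) and Il6 by 0.54 ± 0.15 (0.291). Ccl2 read higher by 0.74 ± 0.14 and Tnfaip3 by 0.54 ± 0.10 (adjusted p = 0.0787 for both). None of these others passed the threshold. In simulated data of the same size and spread, the procedure recovered 62% of genes changed by 0.5 and 90% of those changed by 0.7. The simulation changed 200 genes, whereas 34 were called here. With fewer calls the adjusted threshold is stricter, so these shares can be too high for the real comparison. Smaller changes, such as those read for Tnf and Nfkbia, were not simulated.

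As groups, 11 of the 41 lists lay higher in S534A than in WT livers and 6 lower (camera, preset correlation); 5, all higher, held with an estimated correlation. None of the 14 NF-kB feedback genes passed alone (4 adjusted over the list alone), but 13 read higher, with a median of 0.22 (camera adjusted p = 5.56e-08, or 0.00707 with an estimated correlation). Tnfaip3, Nfkbiz (0.45 ± 0.11) and Rel (0.36 ± 0.10) had the smallest p among them. Of 18 chemokines 2 passed, Ccl3 (0.95 ± 0.11; adjusted p = 0.00386) and Cxcl11 (0.62 ± 0.10; adjusted p = 0.0385), or 6 adjusted over the list alone (median 0.18; camera adjusted p = 1.13e-09, or 0.0196 with an estimated correlation). Ccl7 read 0.91 ± 0.18 higher (adjusted p = 0.0787). Of 22 cytokines 3 passed, Il1a, Il33 and Il1b, or 8 adjusted over the list alone (median 0.11; camera adjusted p = 1.25e-08, or 0.0379 with an estimated correlation); Csf1 read 0.38 ± 0.08 higher (adjusted p = 0.126).

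Of 17 interferon-gamma GTPase and antigen processing genes 1 passed, Cd274 (0.91 ± 0.11; adjusted p = 0.00386), or 2 adjusted over the list alone (median 0.22; camera adjusted p = 7.3e-11, or 0.039 with an estimated correlation). Gbp5 read 0.44 ± 0.12 higher (adjusted p = 0.251). Of 13 neutrophil markers 2 passed, Retnlg (0.68 ± 0.10; adjusted p = 0.0158) and S100a9 (0.52 ± 0.09; adjusted p = 0.0385), or 6 adjusted over the list alone (median 0.45; camera adjusted p = 1.44e-08, or 0.0379 with an estimated correlation). Cxcr2 and Csf3r, neutrophil receptor genes, read 0.60 ± 0.14 and 0.45 ± 0.10 higher (adjusted p = 0.17 and 0.131). The mean over the neutrophil markers was 6.96 ± 0.12 (SD) in S534A and 6.66 ± 0.09 in WT LPS livers. This is a difference of 0.30 (95% interval 0.15 to 0.45, two-sided exact permutation p = 0.0286, the smallest possible with 4 against 4). The means of 7 other lists were higher with full separation too, and none was lower that way. Of these the 4 platelet markers did not pass in camera (0.13; 95% interval 0.01 to 0.26; exact permutation p = 0.0286, not adjusted over the lists, of which 1.2 are expected to separate by chance).

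The estimated-correlation calls of these 5 lists leaned on single arrays. That of the NF-kB list was lost without WT LPS replicate 2 (adjusted p = 0.0566), and that of the chemokines without S534A LPS replicate 1 or WT LPS replicates 1 or 2 (up to 0.0819). That of the cytokines held only without WT untreated replicate 2, S534A LPS replicate 3 or WT LPS replicate 4 (up to 0.125 otherwise). For the neutrophil markers it held only without one of these 3 or S534A LPS replicate 2 (up to 0.152), and for the interferon-gamma list only without WT untreated replicate 2 (up to 0.152). Without the 3 arrays with pancreas transcripts none of the 5 held (adjusted p = 0.0768 for the NF-kB list, chemokines and cytokines, 0.244 for the interferon-gamma list and 0.217 for the neutrophil markers), while all 5 passed with the preset correlation there and with each array left out.

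The other 12 lists that passed with the preset correlation did not hold with an estimated one. All 28 type I interferon genes read higher in S534A livers, by a median of 0.19, and none passed alone (8 adjusted over the list alone; camera adjusted p = 3.5e-15, and adjusted p = 0.115 with an estimated correlation). Mx2 read 0.82 ± 0.16 and Irf1 0.54 ± 0.11 higher (adjusted p = 0.0875 for both). In the IL-6 family and STAT3 list Socs1 passed, and Pim1 read 0.56 ± 0.10 higher (adjusted p = 0.0552; 2 of 13 adjusted over the list alone; camera adjusted p = 0.00699, and adjusted p = 0.115 with an estimated correlation). In the Toll-like receptor list none of 19 passed (4 adjusted over the list alone; camera adjusted p = 0.000439, and adjusted p = 0.235 with an estimated correlation); Tlr3 read 0.53 ± 0.11 and Nod1 0.38 ± 0.08 higher (adjusted p = 0.0903 and 0.115). The endothelial activation, immediate early and cell survival lists also lay higher, with no member past the threshold (adjusted p = 0.137, 0.409 and 0.233 with an estimated correlation).

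The 6 lists that lay lower held no gene past the threshold either. Among the sinusoidal endothelial markers Oit3 read lower by -0.30 ± 0.09 and Kdr by -0.38 ± 0.13 (list median -0.15; camera adjusted p = 0.000439, and adjusted p = 0.44 with an estimated correlation). The heat shock list had a median of -0.15 (camera adjusted p = 0.00699, and adjusted p = 0.137 with an estimated correlation), with Hsph1 as above and Dnaja1 at -0.22 ± 0.11. In the P450 list the 2 genes with the smallest p, Cyp3a25 (0.34 ± 0.09) and Cyp3a11 (0.55 ± 0.17), read higher although the list median was -0.16 (camera adjusted p = 0.0101, and adjusted p = 0.475 with an estimated correlation). In the glucocorticoid list Sgk1 read 0.42 ± 0.13 higher and Zbtb16 differed by -0.28 ± 0.09 (median -0.23; camera adjusted p = 0.0235, and adjusted p = 0.335 with an estimated correlation). The gluconeogenesis and growth hormone lists lay lower as well (adjusted p = 0.233 and 0.395 with an estimated correlation). Each of the 8 LPS arrays, left out, ended the preset-correlation call of at least 1 of these 12 lists. Without the 3 arrays with pancreas transcripts 6 of them lost it: the IL-6 family (camera adjusted p = 0.0525), gluconeogenesis (0.146), Toll-like receptor (0.239), glucocorticoid (0.303), endothelial activation (0.393) and cell survival lists (0.408).

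The acute phase proteins showed no detectable shift. None of 23 passed, nor adjusted over the list alone. The median was 0.02 and the mean -0.01 (camera adjusted p = 0.934, or 0.973 with an estimated correlation). Cd14 read 0.63 ± 0.17 higher (adjusted p = 0.291) and Orm3 differed by -0.72 ± 0.30 (adjusted p = 0.758). Kupffer cell and monocyte markers showed none either (camera adjusted p = 0.934 and 0.806, or 0.973 and 0.879 with an estimated correlation). With the preset correlation the Kupffer cell list lay lower in S534A livers without WT LPS replicate 2 (camera adjusted p = 0.014) and without the 3 arrays with pancreas transcripts (2.66e-05), and it did not pass there with an estimated one (0.398 in the latter). The Kupffer cell marker mean differed by 0.0085 with a 95% interval of -0.31 to 0.33 (exact permutation p = 0.971).

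Genes that LPS raised lay higher in S534A than in WT livers as a set. The set was taken from the mean of both LPS groups against untreated livers, a contrast that weights both genotypes alike, although a gene higher in S534A livers alone can enter it. Over the 481 genes raised at least 2-fold, the median S534A minus WT difference was 0.24, and 430 of them (89.4%) read higher in S534A livers (camera p = 5.11e-55, or p = 0.00195 with an estimated correlation). Of these, 20 were among the 33 genes called higher. Without WT LPS replicates 1 and 2 in turn the median was 0.29 and 0.19, and without the 3 arrays with pancreas transcripts it was 0.15 (p = 0.0539 with an estimated correlation). Over the 236 genes lowered at least 2-fold, the median was -0.08 and 74 (31.4%) read higher (camera p = 5.12e-08, and p = 0.178 with an estimated correlation). Without WT LPS replicate 2 that median was -0.15 (p = 0.0335 with an estimated correlation), and without the 3 arrays with pancreas transcripts it was -0.14 (p = 0.0407).

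Of the 33 genes called higher in S534A livers, 27 were also raised by LPS in the WT comparison and 0 were lowered. Among the called genes 81.8% were raised, against 9.2% of the others (Fisher's exact test, two-sided, odds ratio 44.2, p = 8.54e-23). Genes are not independent of each other, so this p is too small, and the WT LPS arrays enter both comparisons, with opposite signs.

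**Figure D3:**
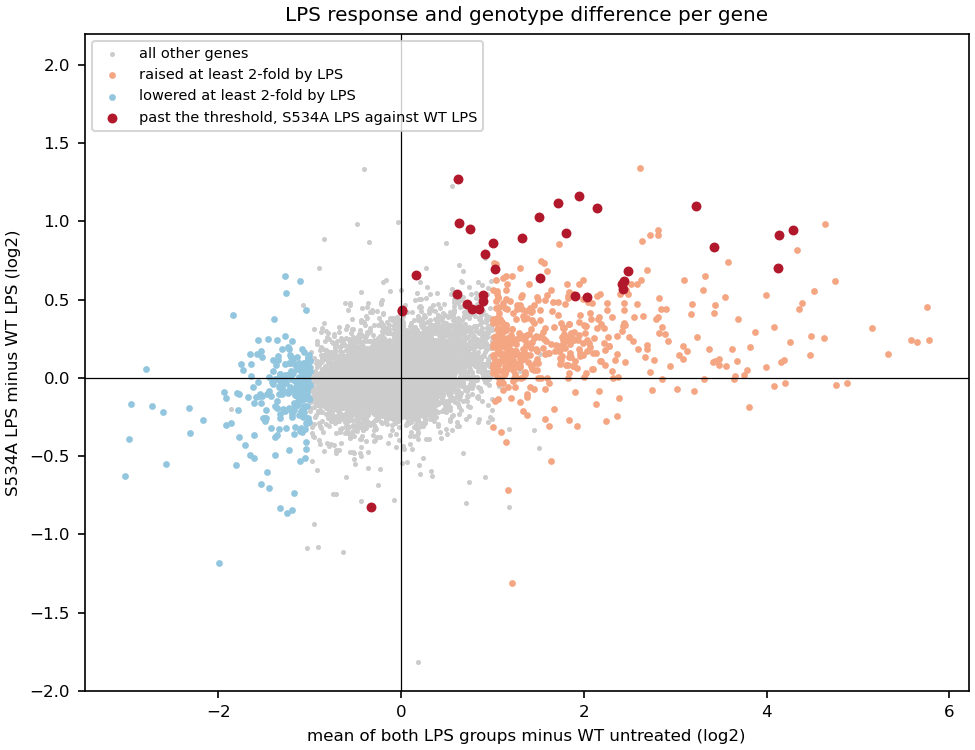
Each point is 1 of 19938 genes. The x axis gives the mean of both LPS groups minus WT untreated and the y axis S534A LPS minus WT LPS, both in log2; colour marks the 481 genes raised and the 236 lowered at least 2-fold by LPS and the 34 genes past the threshold on the y axis, of which 33 lie above 0.

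The called genes were also set against their position, since DNA from the stem cell strain can stay around a targeted gene after backcrossing. Within 20 Mb of Rela on chromosome 19, by the GRCm38.p6 gene table used for neighbourhood only, 0 of 380 genes were called, against 34 of 19476 elsewhere (Fisher's exact test, two-sided, odds ratio 0, 95% interval 0 to 5.89, p = 1). A count of 0 of 34 allows a share of up to 10.3% of the called genes (Clopper-Pearson, 95%). On the whole chromosome 3 of 675 were called, Cd274, Ch25h and Il33 (Fisher's exact test, two-sided, odds ratio 2.76, 95% interval 0.538 to 8.87, p = 0.108). Among all chromosomes the smallest p were those of chromosomes 6 and 18. On these, 5 of 1099 and 3 of 471 genes were called (Fisher's exact test, two-sided, p = 0.0377 and 0.0461). Neither passed after adjustment over the chromosomes (adjusted p = 0.507 for both).

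S534A LPS livers were last compared with untreated WT livers, which differ in both genotype and treatment. Here 2188 genes were higher and 3181 lower (limma, adjusted p under 0.05), 549 and 270 of them by at least 2-fold. Rela differed by 1.24 ± 0.07 (adjusted p = 5.04e-08). The untreated arrays are the same as in the WT comparison, so the counts of both comparisons share the chance values of those arrays.

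Measured differences between arrays of one group stand beside these values. The mean of 6 exocrine pancreas markers was 9.89 on S534A LPS replicate 3, 8.74 on WT LPS replicate 2 and 7.14 on WT LPS replicate 3, against 6.06 to 6.64 on the other 9 arrays. As a list these markers did not differ between groups (camera adjusted p = 0.286 for WT LPS against untreated, 0.934 for S534A against WT LPS), but without S534A LPS replicate 3 they did with the preset correlation (0.0459 and 1.33e-05), and not with an estimated one (0.554 and 0.257). The clock score, the mean of evening-phase minus that of morning-phase clock genes, was -1.93, 2.49, -2.56 and 2.51 on untreated replicates 1 to 4. It ran from -1.36 to -0.16 on the WT LPS arrays and from -1.85 to -0.37 on the S534A LPS arrays.

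**Figure D4:**
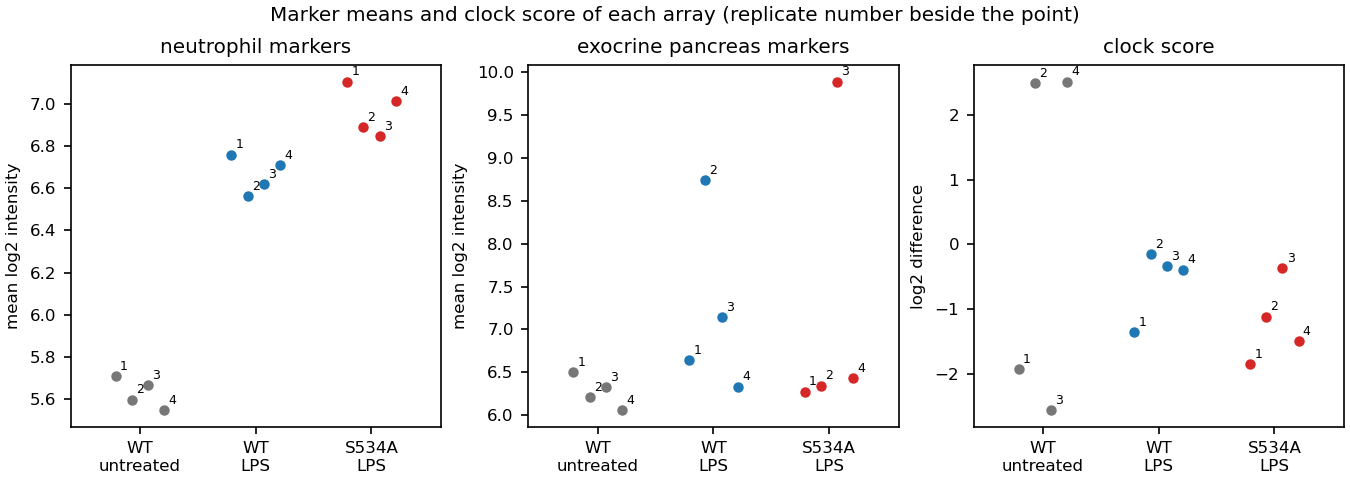
Value of each array, by group on the x axis, with its replicate number beside the point: the mean log2 intensity of 13 neutrophil markers (left), the same for 6 exocrine pancreas markers (middle), and the clock score as a log2 difference (right). The 4 S534A LPS arrays lie above the 4 WT LPS arrays for the neutrophil markers, S534A LPS replicate 3 (9.89) and WT LPS replicate 2 (8.74) stand out for the pancreas markers, and the untreated arrays spread widest in clock score.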

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

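In each group of 4 arrays, the highest or lowest array was compared with the rest for every named gene and every list mean, by Dixon's gap ratio with the critical value 0.829. The tests of pancreas transcripts and of a compressed range given here were chosen after the values were seen. Chance alone marks about 1 in 20 groups, or 25.4 of the 507 tested; 20 were marked, 18 of 384 for genes and 2 of 123 for lists, so the number gives no sign of an excess. All values are the array minus the mean of the other 3 of its group, in log2.

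Among WT LPS arrays, replicate 2 stood apart for Cyp3a25 (-0.262), Kdr (-0.458), Rel (-0.386) and Retnlg (-0.322), replicate 3 for Nfkbia (0.059), and replicate 4 for Bambi (-0.257), Igfals (0.216) and Lrat (0.626). Among S534A LPS arrays, replicate 1 did so for Gbp9 (0.068), Mxd1 (-0.343) and Tlr3 (-0.343), replicate 3 for Adh6-ps1 (0.085), Hsd3b5 (0.123) and Reg3g (0.06), and replicate 4 for Marco (0.683). Among untreated arrays, replicate 1 stood apart for Fam13a (-0.814), replicate 2 for Slfn10-ps (0.327) and the sinusoidal endothelial marker mean (-0.139), and replicate 4 for Mx2 (0.503). The exocrine pancreas marker mean of S534A LPS replicate 3 lay 3.54 above the rest of its group.

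Outside the gene tests, 13767 probe sets had no symbol or several. With the same limma test, 1864 of these were called between WT LPS and untreated livers (735 higher and 1129 lower), and 2 between S534A and WT LPS livers, both higher.

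WT LPS replicate 2 differed by more than 2-fold from the mean of the other 3 arrays of its group in 44 genes, 19 higher and 25 lower, against 9 to 26 genes on the other WT LPS arrays. Such counts were 13 to 38 on the S534A LPS arrays and 57 to 83 on the untreated ones, so it stood out within its group alone. Of the 19 higher, 15 were also more than 2-fold higher on S534A LPS replicate 3, the array with the highest pancreas marker mean. They include the digestive enzyme genes Cpa1 (3.42 on the first array and 4.75 on the second) and Ctrb1 (3.25 and 4.88), named here after their values were seen, so pancreatic tissue taken with the liver is a candidate source of these.

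The 25 genes lower on WT LPS replicate 2, led by Mfsd2a (-1.48), Onecut1 (-1.46) and Cish (-1.46), also named after their values were seen, need another source. On S534A LPS replicate 3, which carried more pancreas signal, their median difference was 0.1251, and 0 of them were lower by 2-fold. A compressed range of the array is argued against as well, since 19 of the 25 stayed more than 2-fold lower after the arrays were quantile normalised again. RNA quality and the state of the animal stay open, untested, and no biological explanation was tested, since the design puts all 4 WT LPS arrays in 1 group.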

How the results depend on the processing

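The fit without the 3 arrays with pancreas signal and the fits with the neutrophil and clock covariates were chosen after the results were seen; the other alternatives were set in advance. Of 77 named genes called between WT LPS and untreated livers, 1693 of 1771 values under the alternatives kept direction and call, 70 kept direction alone and 8 changed sign. For the 34 genes called between genotypes, 501 of 781 values kept both, 280 kept direction alone and 0 changed sign. The number of arrays and the signal over background of dim genes limit all of these.

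Between WT LPS and untreated livers, the count of genes higher (1863) was 1223 at an adjusted p under 0.01 and 417 at 2-fold or more, and 1545 to 1964 with single arrays left out. The count lower (3120) was 1920, 205 and 2613 to 3148, and 1745 without the 3 arrays with pancreas signal, where fewer arrays remain. Between S534A LPS and untreated livers, the count higher (2188) was 549 at 2-fold or more and 1842 to 2590 with single arrays left out. The count lower (3181) was 2096 at an adjusted p under 0.01, 270 at 2-fold or more and 2659 to 3620.

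Between the genotypes after LPS, the count higher (33) was 9 at an adjusted p under 0.01, 70 under 0.1, 6 at 2-fold or more, 19 over every probe set, 344 with array weights and 1 without the 3 arrays with pancreas signal. With single arrays left out it ran from 9 (without WT LPS replicate 3) to 117 (without WT LPS replicate 1). The count lower (1) was 0, 9, 0, 0, 132 and 0 under these settings, 0 to 6 with single arrays left out, 2 with the filter on dim genes, 2 with trend and robust eBayes, 7 after quantile normalising again, 2 after median centring and 3 with the clock covariate. Array weights called all 34 of the same genes. Fewer arrays and stricter thresholds leave less power, which cannot account for the rise to 117 without WT LPS replicate 1. The cause of that rise and of the changes under the other settings was not tested. The median of the 34 genes stayed between 0.58 and 0.74.

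With a replicate block, 17 genes were higher and 0 lower between the genotypes. Samples of the same number did not pair: their correlations after removing group means ran from -0.27 to 0.21, so the numbers give no reason to block.

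The median genotype difference over LPS-raised genes (0.24) was 0.15 without the 3 arrays with pancreas signal (p = 0.0539 with an estimated correlation), 0.0798 with no fold threshold on the LPS response (p = 0.00466 with an estimated correlation), 0.17 with the neutrophil covariate (p = 0.0473 with an estimated correlation), and 0.19 to 0.29 with single arrays left out. That over LPS-lowered genes (-0.08) was -0.24 at a response of at least 4-fold (limma camera p = 0.0269 with an estimated correlation). Without the arrays with pancreas signal it was -0.1449 (limma camera p = 0.0407 with an estimated correlation). With no fold threshold it was -0.0146 and with the neutrophil covariate -0.0177 (p = 0.382 and 0.908 with an estimated correlation). It was -0.153 to -0.0403 with single arrays left out, of which WT LPS replicate 2 alone gave a p under the threshold (0.0335). The cause was not tested. Estimated correlations took the lists called from 20 to 13 for WT LPS against untreated and from 17 to 5 between genotypes. With single arrays left out these were 18 to 22, and 9 (without WT LPS replicate 1) to 19. Near Rela, the odds ratio of 0 became 2.757 for the whole chromosome (Fisher's exact test, p = 0.108), a wider set of genes.

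The neutrophil marker mean rises with LPS, so as a covariate it overlaps with the groups. This widens the error of the group differences, and their sizes can move either way. With it, 39 genes were higher and 5 lower in WT LPS than in untreated livers, 3 and 0 in S534A LPS than in untreated livers, and 0 and 0 between the genotypes. Signs changed for Nr1i3 (0.94), Abcc2 (0.11), Stard4 (0.50), Srebf1 (0.57), F13a1 (-0.14), Lyve1 (-0.63), Lrat (0.85) and Creld2 (-1.73) in WT LPS against untreated livers, and between genotypes for Orm3 (0.081) and Saa1 (0.002), neither called. Saa1, whose difference is near 0, also changed sign with the clock covariate (0.0139) and ran from -0.0643 to 0.0012 with single arrays left out, above 0 only without WT LPS replicate 4.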

Other observations

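Several groups of liver genes did not pass as lists after LPS in WT mice, though members changed. Of 24 immediate early genes 5 rose, the same count adjusted over the list alone, led by Ier3 (0.80 ± 0.11, SE) and Fosl2 (0.37 ± 0.08; camera adjusted p = 0.0541). In the growth hormone list, 1 of 11 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.0599), among them Hsd3b5 (-1.53 ± 0.11) and Igfals (-0.68 ± 0.11), both hepatocyte genes that depend on growth hormone. Of 10 gluconeogenesis and insulin response genes 2 rose and 3 fell (5 and 3 adjusted over the list alone), and the median (0.07) and mean (-0.13) differed in sign; Irs1, the insulin receptor substrate gene, fell by 2.04 ± 0.11 (camera adjusted p = 0.894). Of 17 PPARalpha targets 2 rose and 5 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.239), and of 16 clock genes 2 rose and 4 fell (2 and 5; 0.342). The NRF2 (3 up, 3 down of 10; 0.278), heat shock (2 up of 10; 0.143) and complement and coagulation lists (2 up, 3 down of 18; 0.481) did not pass either.

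Nor did the cell cycle list (0 of 13 called; 0.342) or the markers of hepatocytes (0.481), pericentral (0.173) and periportal hepatocytes (0.562), cholangiocytes (0.744), T and NK cells (3 of 13 rose; 0.137), B cells (0.165), dendritic cells (0.802), platelets (0.137), erythroid cells (0.995) and adipocytes and mesothelium (0.495). With the preset correlation the immediate early genes passed without untreated replicate 2 (0.00195), S534A LPS replicates 1, 3 or 4 or WT LPS replicate 1, and the growth hormone list without untreated replicate 2, S534A LPS replicate 1 or WT LPS replicate 4 (0.0259). None of these lists passed with an estimated correlation, with all arrays or with any 1 left out. Between the genotypes after LPS, no member was called in the lists of bile acid synthesis (camera adjusted p = 0.0826), PPARalpha targets (0.0826), lipogenesis (0.289), the unfolded protein response (0.289), the clock (0.341), NRF2 (0.444), cholesterol synthesis (0.562), complement (0.7) or the cell cycle (0.794), and none of these lists passed. As lists, platelet markers (0.0843), T and NK cells (0.42), dendritic cells (0.428), adipocytes (0.444), erythroid cells (0.459), hepatocytes (0.567), periportal (0.699) and pericentral hepatocytes (0.711), stellate cells, cholangiocytes and B cells (0.7 each) did not pass either. Without the 3 arrays with pancreas signal the bile acid and cholesterol lists did, with the preset correlation only (0.00153 and 0.000768). With single arrays left out, the bile acid list passed that way without S534A LPS replicates 2 or 3 or WT LPS replicate 2, the cholesterol list without S534A LPS replicate 3 (0.00535), and lipogenesis without S534A LPS replicate 1 (0.0257). The PPARalpha targets did so without untreated replicates 2 or 4, S534A LPS replicate 1 or WT LPS replicate 3 (0.0189).

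The tests of a longer segment around Rela and of the clock genes given here were chosen after the results were seen, as were the neutrophil covariate, the excess over a predicted share and the size on arrays left out; the others were planned. Of the 35 ways to split the 8 arrays of a comparison into 4 and 4, 1 (the real one) gave as many called genes in each case. This was 4983 for WT LPS against untreated livers, with 84 the highest of the others, 34 between the genotypes, with 0, and 5369 for S534A LPS against untreated livers, with 0. For the genotypes this argues against chance alone at the 0.05 level, with the smallest share that 35 splits allow. It does not show that each called gene is real. In the comparisons with untreated livers a mixed split puts the LPS response into the spread. Such a split could hardly call as many genes, so those tests decide little. A batch that follows the untreated group or the genotype is not excluded.

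For the 33 genes higher in S534A livers, several sources were weighed. Local effects of donor chromosome within 20 Mb of Rela are argued against as the source of most of the set. There 0 genes were called, which allows up to 10.3% of the called genes. Local effects of a longer stretch of chromosome 19 are argued against likewise by 31 of the 34 called genes on other chromosomes. Donor segments left on other chromosomes stay open. Counts per chromosome gave no excess past the threshold (Fisher's exact test, smallest adjusted p = 0.507), but they could miss a short segment. Position cannot decide on a donor variant that acts on genes elsewhere. For the 3 on chromosome 19, Cd274, Ch25h and Il33, a longer stretch cannot be told apart from chance (odds ratio 2.76, 95% interval 0.538 to 8.87). WT LPS replicate 2 alone is argued against by the median of the 33 genes without it, 0.67, with 20 of them still called. Without other arrays fewer of the 34 genes stayed called: 9 without WT LPS replicate 3, 15 without replicate 4 and 12 to 14 without single S534A arrays. Their median stayed between 0.65 and 0.73 there. Fewer arrays leave less power, so the count of calls kept cannot decide on any single array. Called genes are chosen for their size, so 33 genes were also chosen without 1 array of each genotype and read on those 2. Over the 16 such pairs their median difference averaged 0.61 (95% interval 0.36 to 0.85). More Kupffer cells would have to raise their own markers by about as much, and these differed by 0.0085. The upper bound of the 95% interval of that marker difference, 0.33, misses the 0.3 set in advance. It lies below 0.36 by a small margin, but that bound was chosen after the results were seen. LPS also moved single markers both ways (Marco up, Clec4f and Vsig4 down), so their mean is no count of cells. The markers thus gave no sign of more Kupffer cells but do not exclude them as the source of the set. A change within these cells stays open, untested.

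A stronger response of every LPS-raised gene predicts a median of 0.2059 against 0.70 read. That is under the bound set in advance, 50% of the value read. It is not under 50% of the lower end of the size on arrays left out (0.36), a bound chosen after the results were seen. On those arrays the prediction averaged 0.19, below the 95% interval of the size read there (0.36 to 0.85) and below the lowest of the 16 pairs (0.29). These values argue against a stronger response as the full source of the size of the set, in a comparison also chosen after the results were seen. The 16 pairs share arrays and are not independent of each other. Whether it accounts for 50% of the size is not decided by the bounds above. Gene by gene a stronger response stays open for most of the 33. Tested over all genes, the excess over the predicted share passed for 4 of the 33 (limma, adjusted p under 0.05): Il1a, Il33, Mxd1 and Socs1. The excess was positive for all 33, with a median of 0.43, and 32 had an unadjusted p under 0.05 (limma). These counts lean high, since the 33 were picked for their difference. The test takes the share as known, although it was estimated from the same arrays.

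More neutrophils in S534A livers stay open as a candidate explanation too. Their marker mean was higher by 0.3014, with all 4 S534A arrays above all 4 WT LPS arrays. The platelet marker mean was separated likewise (0.13), but that list did not pass (camera adjusted p = 0.0843, or 0.233 with an estimated correlation). With the neutrophil marker mean as a covariate all 33 genes kept their sign, the median went from 0.70 to 0.59 and the median SE from 0.10 to 0.17, and 0 were called, at which point the wider error ends the calls more than the size. Of the 33, 17 differ by more than the neutrophil gene Retnlg (0.68). An effect of the substitution within liver cells, the biological explanation the design names, may act beside this and cannot be separated from it in whole liver.

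Clock genes spread widely among the untreated arrays. The score was -1.93, 2.49, -2.56 and 2.51 on replicates 1 to 4, and its SD of 2.7521 compares with 0.54 in WT LPS and 0.64 in S534A LPS livers. Evening and morning genes moved in opposite directions on 4 of 4 untreated arrays: Dbp read 8.14, 11.19, 7.59 and 11.39, and Arntl 9.03, 6.29, 9.08 and 6.20. Among 1000 random gene sets the highest SD was 0.744, which argues against a deviation of the whole array, so collection at different times of day may be behind the spread. Collection times are not given in the sources used here, and no biological explanation was tested.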
